A study of Homo sapiens with 4 samples.

How the data were processed

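Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map PPARG, a ligand-activated nuclear receptor that regulates lipid and glucose metabolism, in 2 human lung adenocarcinoma cell lines, NCI-H1993 and NCI-H2347. Per the labels, each line carried a bacterial artificial chromosome (BAC) transgene encoding PPARG fused to a LAP tag (a localization and affinity purification tag that contains EGFP), and the tagged protein was precipitated from formaldehyde-fixed, sonicated chromatin with a goat antibody against EGFP. The 4 samples were 1 ChIP library and 1 input library (chromatin without precipitation) per cell line. The peak lists of the 2 ChIP samples were analysed, and the input libraries were not analysed here. The labels state no ligand treatment. The abbreviation PIO in the names of both lists is not explained in them.

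Each list gave the chromosome, start, end, name and score of every peak, in 5 columns. Per the submitters' processing notes, the lists were made with MACS 1.4.2 on genome build hg19. The aligner, the read filters, the threshold and the way the input libraries entered the calling were not given in the sources used here. The score is deposited as the authors' own value for each peak and was used only to rank and filter peaks within a list. The lowest deposited score was 50.03 in NCI-H1993 and 50.05 in NCI-H2347, just above 50, as a score that is a multiple of the −log10 p-value would be at a fixed calling threshold. Peaks were called on single libraries, so no replicates were pooled. Peak numbers ran to 1419 and 2225, the number of rows in each list, so no peak number was missing. Read depth is unknown from such lists. A deeper library yields more and higher-scoring peaks, so neither peak number nor score was compared between the lines as a measure of binding. Starts were converted to 1-based positions, and all coordinates are on hg19.

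Peaks of the lists were called shared when they overlapped by at least 1 bp. The number shared was compared with 100000 placements of the NCI-H1993 peaks at random on their own chromosomes, between the first and the last peak of either list (one-sided permutation test). Scores of shared and unshared peaks were compared within each list by the difference in mean rank (two-sided permutation test, 100000 permutations), and widths were compared in the same way after the data had been seen. The spread over chromosomes was compared by permuting the list labels over all peaks 100000 times with the chi-square statistic, then by Fisher's exact test for each of 24 classes with Benjamini-Hochberg adjustment. The classes were the chromosomes and, pooled, the contigs, which are sequences outside the assembled chromosomes. Windows of 1 Mb were listed as dense when they held at least 5 peaks and more than the fullest window in 95% of 1000 random placements. Shares carry 95% Wilson intervals, which cover counting error only. There was 1 library per cell line, so every test here compares these 2 lists, treats peaks as independent and has no check by replicates.

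Peaks named in the text were chosen by a rule fixed before the data were examined, except for the wide peaks on chromosome 3 in the closing observations, which were singled out after their values were seen. The rule took the 10 highest-scoring peaks of each list, the 10 shared peaks with the best lower percentile of score across both lists, and per list the 10 highest-scoring peaks with no peak of the other list within 10 kb. The planned annotation by gene feature, the search for 17 motifs and the test of 12 gene lists needed sequence or gene positions on hg19, which were not used here. The gene table at hand was on another build. Peaks are therefore identified by position and not assigned to genes.

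Alternatives fixed beforehand were 50% reciprocal overlap, midpoints within 250 bp, a gap of up to 500 bp, a score of at least 100 in both lists, the longer list cut to the length of the shorter by score, peaks moved by 50 to 500 kb in place of random placement, and windows of 500 kb. Leaving out contig peaks and peaks wider than 2500 bp was added after the data had been seen. The code was tested on simulated lists. Of 200 planted shared peaks, 200 were recovered among 1411, and 4 of 200 simulations of unrelated lists gave p under 0.05. The rank test gave p under 0.05 in 7 of 100 simulations without a difference, and the chromosome test in 4 of 100 with shuffled lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.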

Results

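PPARG binding was mapped by ChIP-seq in 2 lung adenocarcinoma lines that carried EGFP-tagged PPARG, with 1 ChIP library per line. The list of NCI-H1993 held 1419 peaks and that of NCI-H2347 held 2225. Peaks had a median width of 731 bp in NCI-H1993 (quartiles 596 and 906 bp) and 832 bp in NCI-H2347 (685 and 993 bp), and they covered 1.20 Mb and 1.95 Mb in all. The authors' score had a median of 69.8 in NCI-H1993 and 77.1 in NCI-H2347. A score of at least 100 was reached by 338 peaks (23.8%) in NCI-H1993 and by 734 peaks (33.0%) in NCI-H2347. The read depth behind the lists is unknown, and no replicate was available for either line.

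The first comparison asked which genomic sites PPARG occupied in both cell lines. Of the NCI-H1993 peaks, 486 overlapped an NCI-H2347 peak, which is 34.2% of the list (95% Wilson interval 31.8% to 36.8%). In the other direction, 483 NCI-H2347 peaks, or 21.7% (20.0% to 23.5%), overlapped an NCI-H1993 peak, and 3 of them overlapped more than 1. Random placement of the NCI-H1993 peaks on their chromosomes gave 2.00 overlapping peaks on average and 10 at most, so the observed number was 242 times the mean (one-sided permutation test, p = 1e-05, the smallest that 100000 placements can give). Moving each peak by 50 to 500 kb, which keeps the regional density, gave 3.43 on average, and the observed number was 142 times that mean (permutation p = 1e-05). Placed and moved peaks can land where no peak could be called, and peaks common to the lists for other reasons also count as shared. The overlap therefore does not show by itself that shared peaks are PPARG sites. The remaining 933 NCI-H1993 peaks and 1742 NCI-H2347 peaks had no overlapping peak in the other list. Overlapping peaks lay close to each other. Their midpoints were a median of 76.3 bp apart (quartiles 33.5 and 134 bp), and 450 of 486 pairs (92.6%) had midpoints within 250 bp.

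The site ranked highest by both lists together was on chromosome 7. It spanned positions 95237562 to 95238949 in NCI-H1993, where its score of 610 was the third highest of the list, and 95237551 to 95238709 in NCI-H2347, with a score of 410. A site on chromosome 10 followed, at 73099497 to 73100645 in NCI-H1993 with a score of 233 and at 73099450 to 73100569 in NCI-H2347 with a score of 362. Next came a site on chromosome 9, at 110517332 to 110518175 in NCI-H1993 and 110517345 to 110518252 in NCI-H2347, with scores of 223 and 378. Of the other sites in the best 10, 4 were on chromosome 1, starting in NCI-H1993 at 64128566, 153324557, 167411033 and 204140576. The other 3 were on chromosome 6 from 47156017, chromosome 19 from 50268598 and chromosome 20 from 50366358. The chromosome 19 site had the highest score of the NCI-H1993 list, 716, and a score of 296 in NCI-H2347.

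The next comparison asked whether shared and unshared sites differed in the strength of the call. Shared peaks scored higher in both lists. In NCI-H1993 the median score was 86.1 for shared peaks (quartiles 63.8 and 123) and 65.4 for unshared peaks (55.1 and 86.0). In NCI-H2347 the medians were 116 (71.1 and 180) and 72.1 (57.4 and 102). Both differences had p = 1e-05 by the two-sided permutation test of mean rank, the smallest that 100000 permutations can give. The lowest-scoring 10% of the NCI-H1993 list held 14.8% shared peaks (9.88% to 21.6%) and the highest-scoring 10% held 63.1% (54.9% to 70.6%). The corresponding shares in NCI-H2347 were 10.8% (7.34% to 15.5%) and 53.2% (46.6% to 59.6%). Within NCI-H2347, the share stayed between 9.87% and 19.4% in the lower 6 of 10 score bins and was 41.3% in bin 9. Of the 486 overlapping pairs, 89 were in the top 10% of NCI-H1993 by score, 120 in the top 10% of NCI-H2347 and 33 (6.79%) in the top 10% of both. Shared peaks were also wider, with medians of 773 bp against 708 bp in NCI-H1993 (two-sided permutation test of mean rank, p = 0.00033) and 903 bp against 813 bp in NCI-H2347 (permutation p = 1e-05). Among peaks with a score of at least 100 the medians were in the other order in NCI-H1993, 844 bp for shared and 880 bp for unshared peaks (permutation p = 0.17). A wider peak is more easily overlapped, and the score difference was also present when midpoints within 250 bp defined sharing (permutation p = 1e-05 in both lists).

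**Figure D1:**
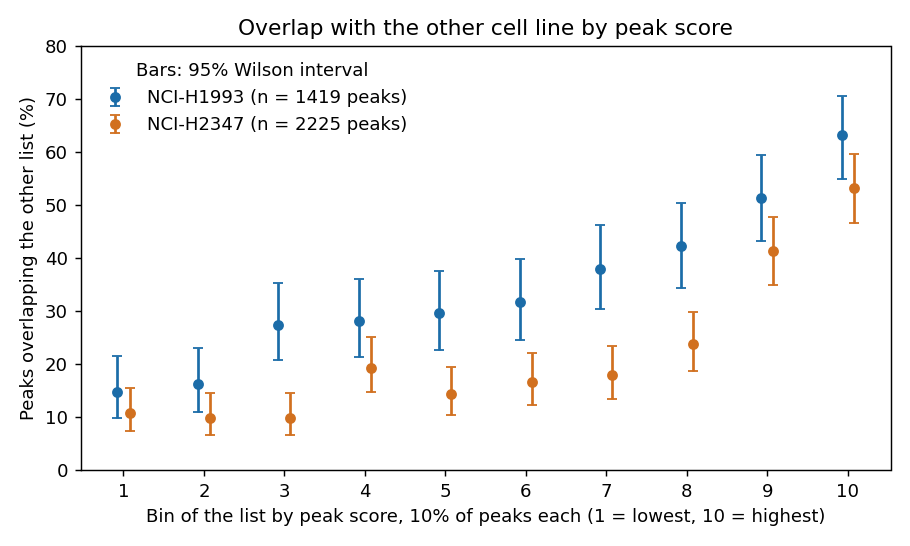
Share of peaks that overlap a peak of the other cell line (y axis, percent) for each of 10 equal bins of a list ordered by the authors' peak score (x axis, 1 lowest to 10 highest). Points are shares within NCI-H1993 (blue) and NCI-H2347 (orange) and bars are 95% Wilson intervals; the share in the highest bin was 63.1% in NCI-H1993 and 53.2% in NCI-H2347.

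Strong sites present in a single list were found in both lines. In NCI-H1993, 52 of the 141 peaks in the top 10% by score had no overlapping peak in NCI-H2347, and in NCI-H2347 the number was 104 of 222. The highest-scoring NCI-H1993 peak with no NCI-H2347 peak within 10 kb was on chromosome 1, positions 121483888 to 121485608, with a score of 651. That peak bordered the longest stretch of chromosome 1 without a peak in either list. Whether unassembled or repeated sequence is its source was not tested, so it cannot be taken as a PPARG site. At 1721 bp it was kept when peaks wider than 2500 bp were left out. The next peak was on chromosome 3, positions 157503935 to 157504939, with a score of 321. Of the 10 highest-scoring such peaks, those ranked 3 and 9 lay close to each other on chromosome 12. They were at 68098581 to 68100447 with a score of 256 and at 67876899 to 67879650 with a score of 215. The latter was wider than 2500 bp. The peak ranked 6, on chromosome 8 from 118823320, also bordered the longest stretch of its chromosome without a peak. The peak ranked 8, on chromosome 19 from 18570560, lay within 3 Mb of that stretch on its chromosome. In NCI-H2347 the highest-scoring peak with no NCI-H1993 peak within 10 kb was on chromosome 17, positions 40935121 to 40936060, with a score of 707. The next were on chromosome 5, positions 14037995 to 14040018, with a score of 661, and on chromosome 1, positions 201435059 to 201436294, with a score of 527. A peak on chromosome 7, positions 142123096 to 142124516, had a score of 482. Absence from a list means that no peak passed the authors' threshold there, since the signal below it was not available in the lists. The highest-scoring peak of NCI-H2347, on chromosome 1 from 178505622 to 178509163 with a score of 1002, was shared.

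The lists were then compared for their spread over the chromosomes. NCI-H1993 had a larger share of its peaks on chromosomes 7 and 16, and NCI-H2347 on chromosomes 11 and 17. The spread differed as a whole (chi-square statistic 85.3 over 24 classes, permutation test p = 1e-05, the smallest that 100000 permutations can give), and 5 classes passed Fisher's exact test with Benjamini-Hochberg adjustment. Both tests treat peaks as independent. Peaks within a list lay in close pairs more often than moved peaks did, so these p-values may be too small. Chromosome 7 held 103 peaks or 7.26% of the NCI-H1993 list (6.02% to 8.73%) and 111 peaks or 4.99% of the NCI-H2347 list (4.16% to 5.97%), with an adjusted p of 0.028. Chromosome 16 held 3.03% (2.26% to 4.06%) and 1.53% (1.10% to 2.13%), with an adjusted p of 0.023. Chromosome 11 held 3.74% (2.87% to 4.85%) and 6.07% (5.15% to 7.14%), with an adjusted p of 0.023. Chromosome 17 held 4.51% (3.55% to 5.72%) and 6.74% (5.77% to 7.86%), with an adjusted p of 0.028. Of the 150 NCI-H2347 peaks there, 12 lay in each of the 1 Mb windows from 48000001 and from 57000001. Contigs held 8 peaks of NCI-H1993 and 0 of NCI-H2347, with an adjusted p of 0.013 by the same exact test. The read filters were not given, so removal of contig reads before calling in NCI-H2347 cannot be told from absence of peaks there. The differences of the 4 chromosomes kept their direction and much of their size under the alternatives, while most calls were lost. Without peaks wider than 2500 bp and contig peaks, chromosome 7 no longer passed (exact test, adjusted p = 0.073), with a difference of 2.05 percentage points against 2.27 with all peaks. With the NCI-H2347 list cut to the length of the NCI-H1993 list by score, chromosome 11 alone passed (exact test, adjusted p = 0.027), and contigs did not (adjusted p = 0.074). Among the 338 and 734 peaks with a score of at least 100, none of the 4 passed (exact test, adjusted p = 0.41 for each). NCI-H1993 minus NCI-H2347, the differences there were 2.11 percentage points for chromosome 7, 1.16 for chromosome 16, -1.95 for chromosome 11 and -2.33 for chromosome 17, against 2.27, 1.50, -2.33 and -2.23 with all peaks. Contigs held 2 and 0 of those peaks (exact test, adjusted p = 0.4), and chromosome 10 passed, with a share 5.40 percentage points higher in NCI-H1993 (exact test, adjusted p = 0.021).

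**Figure D2:**
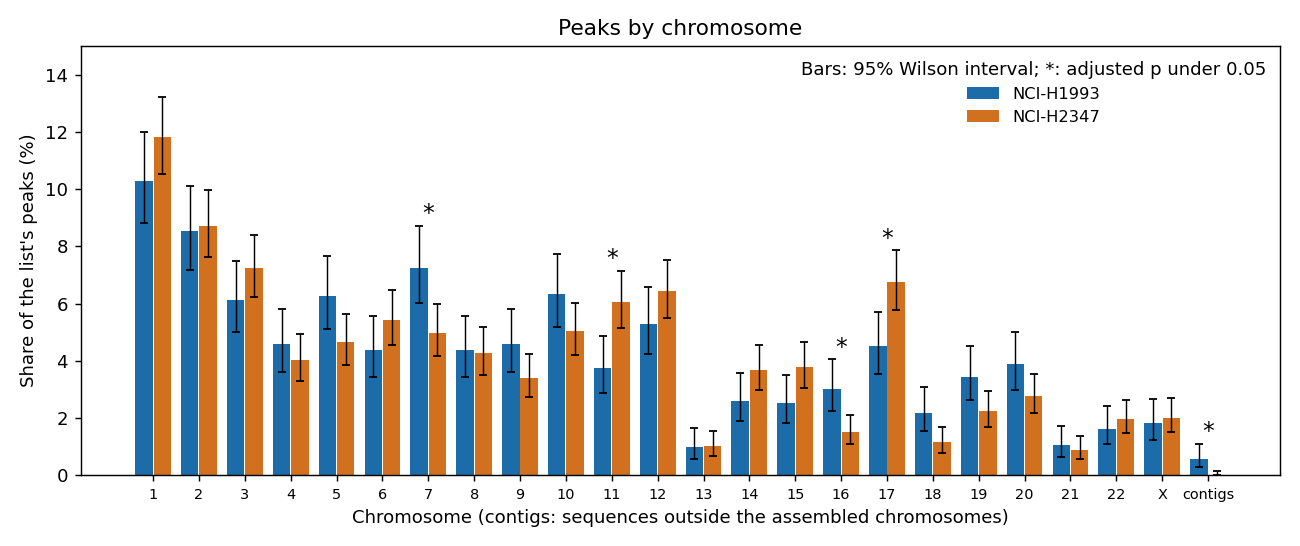
Share of each list's peaks (y axis, percent) on each chromosome and on contigs outside the assembled chromosomes (x axis) for NCI-H1993 (blue, 1419 peaks) and NCI-H2347 (orange, 2225 peaks). Bars carry 95% Wilson intervals and asterisks mark the 5 classes with an adjusted p under 0.05; chromosome 7 held 7.26% of NCI-H1993 peaks and 4.99% of NCI-H2347 peaks.

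Some windows also held more peaks than the fullest window in 95% of random placements on the same chromosomes. These placements did not keep the regional density of peaks, so a window in a region generally rich in peaks can pass. In NCI-H2347, 5 windows of 1 Mb passed, where 95% of placements had no window above 8 peaks. The fullest window of any placement held 10. On chromosome 17, the window from 48000001 to 49000000 held 12 peaks in NCI-H2347 and 1 in NCI-H1993. The window from 57000001 to 58000000 on the same chromosome held 12 peaks in NCI-H2347 and 6 in NCI-H1993, and 5 of the 12 were shared. The other windows were on chromosome 12 from 52000001 with 10 peaks, on chromosome 1 from 201000001 with 9 peaks and on chromosome 11 from 65000001 with 9 peaks. None of these exceeded the 10 peaks that random placement reached. NCI-H1993 had 1 such window, on chromosome 10 from 73000001 to 74000000, with 7 peaks against 2 in NCI-H2347. For NCI-H1993, 95% of placements had no window above 6 peaks, but the fullest window of any placement held 8. The chromosome 10 window contained the second-ranked shared site. No window was listed for both lines (0 windows in common), and the difference in count between the lines was not tested for single windows. With windows of 500 kb, 3 windows passed in NCI-H2347 and 0 in NCI-H1993. Among peaks with a score of at least 100, the window on chromosome 17 from 57000001 was the 1 that passed in NCI-H2347, with 7 peaks, and the window on chromosome 17 from 48000001 did not pass; in NCI-H1993 the window on chromosome 10 passed with 5 peaks.

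**Figure D3:**
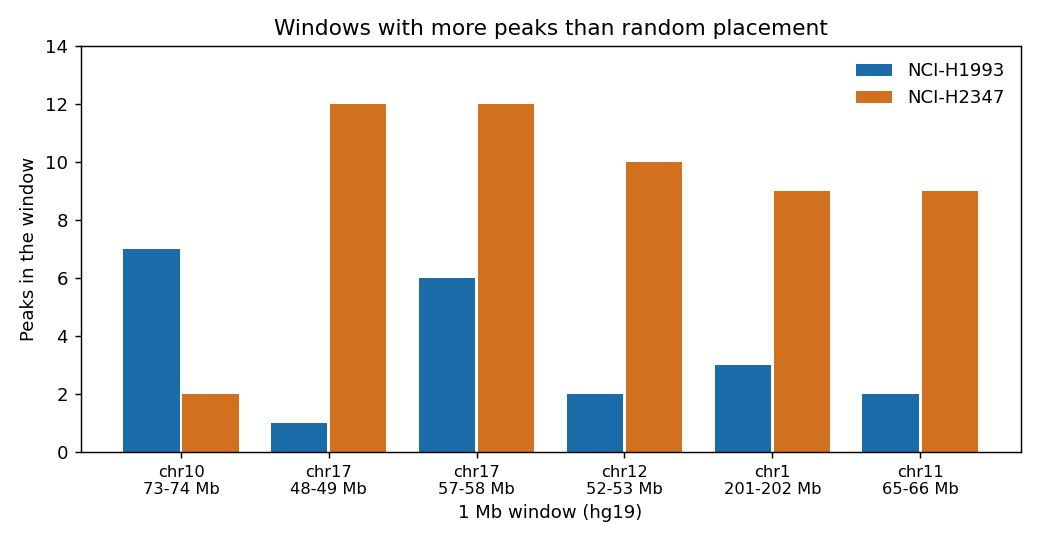
Number of peaks (y axis) in the 1 Mb windows of hg19 (x axis) listed as dense in either line. NCI-H1993 is in blue and NCI-H2347 in orange. The fullest window of any random placement held 8 peaks for NCI-H1993 and 10 for NCI-H2347. Of the windows shown, those on chromosome 17 alone held more than that in the line for which they were listed. The window on chromosome 10 was listed for NCI-H1993, with 7 peaks, and the other 5 for NCI-H2347, with 9 to 12 peaks.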

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

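Leaving out contig peaks and peaks wider than 2500 bp was the 1 alternative chosen after the data had been seen. The number of shared NCI-H1993 peaks was 448 with 50% reciprocal overlap, 450 with midpoints within 250 bp, 492 with a gap of up to 500 bp, 390 with the longer list cut to the length of the shorter and 477 without wide and contig peaks, and each had a permutation p of 1e-05. Moving peaks by 50 to 500 kb in place of random placement gave a mean of 3.43 shared peaks, with the same p. With a score of at least 100 in both lists 129 peaks were shared, from 338 and 734 peaks (permutation p = 1e-05), since fewer peaks were compared. Shared peaks scored higher than unshared peaks in both lists under all 6 alternatives run for that test; the difference in medians ranged from 18.5 to 20.8 in NCI-H1993 and from 38.6 to 47.4 in NCI-H2347, and the largest p was 0.004, for NCI-H1993 among peaks with a score of at least 100. The chromosome statistic was 49.6 with a score of at least 100 (permutation p = 0.00077), 64.1 with the longer list cut and 70.6 without wide and contig peaks (p = 1e-05 for both). The number of classes that passed fell from 5 to 1, 1 and 3 under these alternatives, in that order. The last tested 23 classes, since the contig class was removed and could not pass. The class that passed with a score of at least 100 was chromosome 10, which did not pass with all peaks; the cause was not tested. Windows listed as dense fell from 1 to 0 in NCI-H1993 and from 5 to 3 in NCI-H2347 with 500 kb windows, and from 5 to 1 in NCI-H2347 with a score of at least 100, where fewer peaks were placed. Alternatives for gene features, motifs and gene lists were not run, because neither sequence nor gene positions of hg19 were used. No paired analysis was possible because there was 1 ChIP library per cell line. Depth is unknown, so a site missing from a list cannot be read as unbound.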

Other observations

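The tests of adjacent peaks and of wide peaks were chosen after the lists had been examined, and those of distance to the other list and of neighbourhoods within 2 Mb before their results were seen. Close pairs of peaks within a list were more frequent than among moved peaks, though most peaks were not in one. In NCI-H1993, 60 adjacent pairs of peaks had midpoints within 10 kb, against 16.4 on average and 32 at most when peaks were moved by 50 to 500 kb. NCI-H2347 had 167 such pairs against 44.3 on average and 70 at most (permutation p = 0.0001 in each list, the smallest that 10000 placements can give). The excess was 3.65-fold and 3.77-fold.

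Some sites listed in NCI-H1993 only lay near NCI-H2347 sites. Of 925 unshared NCI-H1993 peaks on the chromosomes, 175 (18.9%) had an NCI-H2347 peak within 50 kb. Moving these peaks by 0.5 to 2 Mb left 73.8 on average and 104 at most, a ratio of 2.37 (permutation p = 0.0001, the smallest possible), which argues against a common density of peaks on the scale of 1 Mb as the whole source. The NCI-H2347 peaks counted were not limited to unshared ones, so an NCI-H1993 peak beside a shared site also counts. Such cases were not counted separately. A hypothesis left open is that the same loci may be bound through different elements in each line. Close pairs of peaks within a list, or peaks clustered by open chromatin on a finer scale, could give the same result. None of these was tested as the source.

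Strong peaks in 1 list only, here the unshared peaks of the top 10% by score, were the second pattern. Whether such sites lay just under the calling threshold in the other line was not tested, since the lists hold no signal below it. Unassembled or repeated sequence was not tested as a source of these peaks either. It stays open for those that border a longest peak-free stretch, such as the highest-scoring one in NCI-H1993. Gained copies of a region may contribute. Among other unshared peaks within 2 Mb, the own list made up 43.4% around unshared top peaks and 35.4% around shared top peaks in NCI-H1993, 8.03 percentage points more (one-sided permutation test, p = 0.029), and 76.3% against 69.9% in NCI-H2347, 6.35 points more (p = 0.01). A regional difference in chromatin between the lines predicts the same excess. Close pairs of peaks within a list could also give it, since both lists can have such neighbours around a shared peak. The excess therefore does not single out gained copies, and copy number itself was not measured here.

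The third pattern was a set of peaks wider than 2500 bp, 25 in NCI-H1993 (9.50% of the bases in peaks) and 9 in NCI-H2347 (2.09%), with a median score of 85.6 against 69.8 for the other peaks in NCI-H1993 and 70.4 against 77.1 in NCI-H2347. Leaving out contigs, 8 of 32 (25%) lay within 3 Mb of the longest stretch of their chromosome without any peak of either list, against 6.13% of the other 3604 peaks (one-sided Fisher's exact test, p = 0.00061). The count was 6 of 23 in NCI-H1993 (exact test, p = 0.003) and 2 of 9 in NCI-H2347 (exact test, p = 0.099). Some of these sites are wide in both lists or lie close together, and with peaks within 500 kb merged over both lists 5 of 20 wide loci (25%) lay there against 7.07% of 1245 others (exact test, p = 0.012). In NCI-H1993, 2 of the 25 wide peaks were on contigs, so outside the assembled chromosomes, and these were not part of the test. For the wide peaks on the chromosomes, whether unassembled or repeated sequence is a source stays open. NCI-H2347 has too few wide peaks, and the stretches were not shown to be unassembled. Most wide peaks lay elsewhere, but such sequence can also lie away from the longest stretch, so their position does not count against it. No biological explanation was tested.

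A pair of wide peaks stood next to each other on chromosome 3 in NCI-H1993, at 12483898 to 12488432 with a score of 62.9 and at 12491164 to 12498868 with a score of 53.2. NCI-H2347 had an overlapping wide peak at 12482638 to 12488264 with a score of 70.4. PPARG itself is a gene of chromosome 3 and both lines carried a BAC with it, but the distance of these peaks from the gene or from the ends of the BAC was not determined. These peaks were singled out after their values were seen.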
